A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

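MNase-seq was run on 12 samples of Saccharomyces cerevisiae BY4741, as 2 biological replicates in each of 6 groups per the series design. Per the labels, cells grew in YPD to mid-log phase and chromatin was digested with 600, 1200 or 2400 gel unit per ml of micrococcal nuclease. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned to sacCer3 with Bowtie2 and handled with SAMtools, without versions. The tool that called nucleosome positions, its smoothing and its treatment of duplicate reads are not given in the sources used here. The deposited lists hold 1 entry per called nucleosome and 1 list per group, so both replicates were pooled by the authors. Per the file headers, each entry has a position in bp (the summit, with an end always 1 bp further), a mean read position and a standard deviation of read positions in bp. The peak height is, per the file headers, the signal at the summit of the authors' track, on a scale that is not stated. The read count of each nucleosome is, per the file headers, a whole number of reads, and the nearly equal totals as deposited show counts brought to a common depth or sequenced alike, which cannot be decided. Smoothed tracks were not used here.

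The pools WT1, WT2, WT3, Ioc3-KO, Ioc3-R739E/R742E and Ioc3-Q251K/D252K listed 76322, 76013, 76238, 77652, 77171 and 76986 nucleosomes. Their assigned reads were 10298802, 10282804, 10284441, 10350515, 10323596 and 10328582, with medians of 137, 139, 138, 133, 136 and 134 per nucleosome. The median fuzziness (standard deviation of read positions) was 31.9, 31.5, 31.9, 33.2, 32.5 and 32.3 bp. Divided by the root of the reads, this gives a median standard error of 2.77 bp for the mean read position, not for the summit. Reads without molecular identifiers are not independent molecules, so this covers counting error only.

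A consensus of 72863 dyads was called from the summits of all 6 pools, smoothed with a Gaussian of SD 20 bp and kept at least 100 bp apart. Each pool's nearest summit within 70 bp was matched, and 67770 dyads (93.0%) were matched in all pools. Coding regions of 6002 genes came from the gene table of the reference, with the strand read from the systematic name. The table holds no UTR and no transcription start, so positions are relative to the start codon, and the coordinate base of the lists is not stated, which shifts all pools alike. The nucleosome-depleted region was the widest consensus gap of at least 200 bp whose middle lay from 400 bp before to 50 bp after the start codon, and 2066 genes had one. Its flanking dyads were numbered -1 and +1, and +2 to +5 followed at less than 220 bp each, up to the end of the coding region. A nucleosome from +2 on can thus lie before the start codon, as +3 of RPL36B did. Nucleosomes matched in every pool were tested.

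Analyses used R 4.3.3 with limma 3.58.1 and edgeR 4.0.16, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. For each nucleosome number, limma (lmFit and eBayes) was fitted to the 6 pools with genotype as the only factor. The residual spread came from the 3 wild-type pools, and each lone pool was assumed to vary like them. The labels name an added wild-type control pair but not which wild-type pool was handled beside which genotype, so all 3 served as reference for every genotype. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Position (bp, positive downstream), fuzziness (bp) and occupancy (log2 peak height over the pool's median) were tested alike. Each wild-type pool was fitted against the other 2. That fit has 1 residual degree of freedom, as do fits with a wild-type pool left out, where the fit of all pools has 2. The 3 Ioc3 pools were fitted against the 3 wild-type pools, with a residual spread from within both groups, so differences between the Ioc3 genotypes enter it. Differences between genotypes were tested as contrasts of 1 pool with 1 pool. Median shifts had exact two-sided permutation tests, which cannot go below 0.25 for 1 pool against 3 or below 0.1 for 3 against 3, with adjustment over a family of 20 measures for the latter. Correlations between genotypes are across genes and were set beside 100 simulations in which only the shared wild-type mean links the genotypes, and beside the 6 assignments of a different wild-type pool to each genotype.

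The comparisons at +1, the median shifts, the distances, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. Calls at -1 and at +2 to +5, occupancy there, fuzziness at +3 to +5, and the genotype differences at +2 and +3 were added afterwards. Named were the 8 largest called shifts in each direction per genotype that lay outside the wild-type range, up to 4 called members of each list, and MET16, PHO8, PHO5, HTA1, GAL1 and ISW1 whatever their result. Of the last, PHO8 alone had a matched +1 nucleosome. The text names a part of the genes this rule takes, and the rule was applied in the same form at the added nucleosomes and measures. Genes of the comparison of 3 with 3 pools and of genotype differences are named from all those called, and BUR2 as a neighbour was chosen after its values were seen.

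Gene lists were cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, histones, glycolysis and fermentation, TCA and respiration, amino acid synthesis, sulfur, phosphate, galactose and carbon-repressed genes, stress, chaperones, mating, meiosis, cyclins, chromatin remodeler subunits, general regulatory factors, divergent and tandem promoters, long, short, subtelomeric and tRNA-adjacent genes. They were matched by symbol, coordinates or neighbours, without the study's results. Lists with enough members, 23 at +1 and +2 and 22 at +3 and for fuzziness at +4, were tested with camera at a preset correlation of 0.01 and again with an estimated one.

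The fits were tested on simulated data with changes added to 200 genes of wild-type-like noise. The counts of unchanged genes called hold for this noise only. Whether it includes summits that jump in a single pool was not tested. In the real data, each wild-type pool had +1 dyads that met the rule of 20 bp outside the range of the other wild-type pools. The simulated counts are thus no estimate of false calls from such jumps in a lone pool. At +1, 31.3%, 68.7% and 86.4% of shifts of 10, 30 and 60 bp were recovered for 1 pool against 3, with 6 unchanged genes called. At +3 the shares were 26.9%, 77.6% and 93.9%, with 5 unchanged genes called. For fuzziness at +4, changes of 3, 6 and 9 bp were recovered in 2.99%, 46.3% and 90.9%, with 0 unchanged genes called, and a log2 occupancy change of 0.5 or 1 in 39% and 99%, with 17 unchanged genes called.

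Alternatives were matching limits of 50 and 90 bp, a consensus from wild-type pools, depleted regions of at least 250 bp or of any width, shifts centred per pool, nucleosomes without the fuzziest or least occupied quartile, robust or trended eBayes, uncentred occupancy, and a rule of 20 bp outside the wild-type range. Each wild-type pool was also left out in turn, for the genotype differences too, and each of the 6 pools in the comparison of 3 with 3 pools. Chosen after seeing the data were the mean read position as dyad, removal of calls with a peak height under 0.3, edgeR on reads, genes outside a segment of chromosome IV, each wild-type pool as the only reference for the median shifts, the mean of all adjacent dyads, the genotype differences without a wild-type pool, and all alternatives for the added counts. That segment was found from reads in 1 kb bins with a depth-scaled count of at least 20, as a run of at least 10 bins with a ratio of at least 1.4 to the wild-type pools. Mitochondrial reads and the marker genes entered no fit.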

Results

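Nucleosome positions were mapped by MNase-seq, the sequencing of DNA left after digestion of chromatin with micrococcal nuclease, in Saccharomyces cerevisiae BY4741 grown in YPD to mid-log phase. The 12 samples formed 6 groups of 2 biological replicates. Of these, 3 groups were wild type (WT1, WT2 and WT3), and the others were a knockout of IOC3 (Ioc3-KO) and the point mutants Ioc3-R739E/R742E and Ioc3-Q251K/D252K. Ioc3 is a subunit of the ISW1a chromatin remodeler, whose ATPase is Isw1. Both replicates of a group were joined in 1 position list, called a pool here, so every wild-type mean had n = 3 pools and every Ioc3 genotype had n = 1 pool without replicate error. The limma p-values of single genotypes therefore measured the spread between wild-type pools only. In limma fits of all 3 Ioc3 pools against wild type, the error also holds the spread between the Ioc3 genotypes. The pools listed 76013 to 77652 nucleosomes with 10282804 to 10350515 assigned reads and a median of 133 to 139 reads per nucleosome. The standard error of a nucleosome's mean read position had a median of 2.77 bp and covered counting error only. Positions are summits unless stated, and the error of a summit was not obtained. Positive shifts are downstream, into the gene, and nucleosomes are counted from the nucleosome-depleted region in front of each gene.

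The knockout was visible at its own locus. IOC3 (YFR013W, chromosome VI, 169922 to 172285, sacCer3) held 16, 16 and 18 nucleosomes in the wild-type pools, with 2392, 2426 and 2570 reads. The Ioc3-KO pool held 5 nucleosomes and 825 reads there, with no summit between 170594 and 172282. Ioc3-R739E/R742E held 16 nucleosomes and 2355 reads at IOC3, and Ioc3-Q251K/D252K held 16 nucleosomes and 2228 reads. ISW1 (chromosome II, 708150 to 711539), the gene of the ATPase, held 21 or 22 nucleosomes in every pool. LEU2, a marker gene deleted in this strain background, had 0 listed nucleosomes in all pools. URA3, another such marker, had 0 listed nucleosomes in every pool except Ioc3-KO, which had 5 nucleosomes and 698 reads there.

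The comparison of Ioc3-KO with wild type asked how loss of Ioc3 shifts nucleosomes along genes. The genic nucleosomes lay downstream of their wild-type positions. The median shift was 1.0 bp at +1 (1993 genes), 2.67 bp at +2 (1896 genes), 2.67 bp at +3 (1855 genes), 2.0 bp at +4 (1724 genes) and 0.667 bp at +5 (1539 genes), against -0.667 bp at -1 (1973 genes). Single wild-type pools set against the other 2 had medians from -0.5 to 0.5 bp at +2 and at +3. At +2, 74.1% of genes lay downstream in the knockout, against 52.7%, 41.7% and 43.6% in WT1, WT2 and WT3. The +1, +2, +3 and +4 medians lay outside the wild-type pools, with p = 0.25 for 1 pool against 3 in an exact two-sided permutation test, the smallest p this design allows. The +1 median changed sign to -0.278 bp when each pool's shifts were centred on the pool's median, while +2 and +3 both stayed at 1.39 bp.

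**Figure D1:**
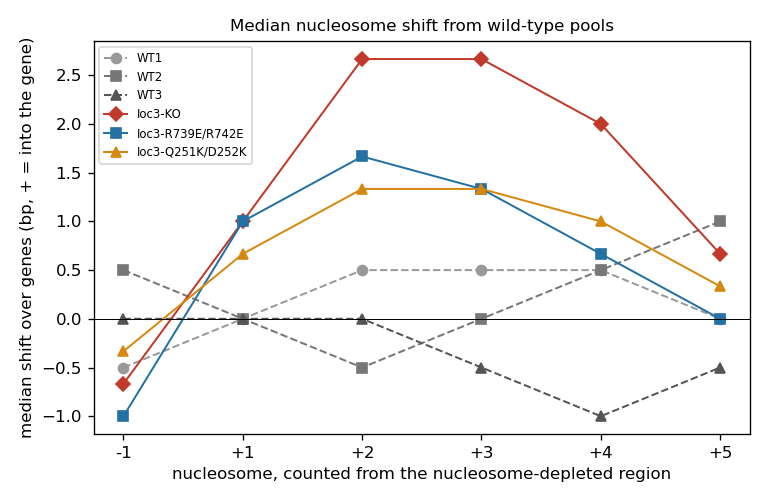
Median shift in bp over genes (vertical axis) of the -1 to +5 nucleosomes (horizontal axis) in each pool, wild-type pools dashed and each set against the other 2, Ioc3 pools solid and set against the 3 wild-type pools. At +2 the Ioc3-KO, Ioc3-R739E/R742E and Ioc3-Q251K/D252K medians were 2.67, 1.67 and 1.33 bp, and the wild-type medians lay from -0.5 to 0.5 bp.

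At +3, 57 genes changed position in Ioc3-KO (limma, adjusted p under 0.05), 47 of them downstream and 10 upstream. SKM1 (chromosome XV, dyad 104700), a kinase of the PAK family, and its divergently transcribed neighbour PTH4 (dyad 103895) both moved 67.0 bp downstream (SE 2.07, adjusted p = 0.0178). NIT2 (chromosome X, dyad 184838) moved 63.0 bp (SE 0.893, adjusted p = 0.00941), from 336 bp after its start codon in each wild-type pool. RPL36B, a cytosolic ribosomal protein gene, moved 66.3 bp, and YPR127W, ALG13, DIA2 and CUP9, the last a transcriptional repressor, moved 64.0, 62.7, 62.0 and 57.0 bp. The upstream shifts included DLD3 at -71.3 bp (SE 2.99), PUN1 at -48.3 bp, APQ12 at -42.7 bp and AGE1 at -16.0 bp. REB1 (chromosome II, dyad 336682), which encodes a general regulatory factor, had an upstream shift of -36.3 bp (SE 2.99, adjusted p = 0.0466). Further called genes were HSP104, the disaggregase gene, at 24.3 bp (SE 1.68), ATP16, an ATP synthase subunit gene, at 24.7 bp (SE 1.04) and RPL23B at -23.3 bp. SNX3 and SHG1, both short genes, moved 54.7 and 51.0 bp. CTF19, in the phosphate list and known as a kinetochore gene, moved 17.3 bp. Multicopy sequence adds uncertainty for YHR218W at 49.3 bp, YRF1-4 at 52.7 bp and the overlapping Ty reading frames YCL019W and YCL020W, which share 1 nucleosome, at -33.3 bp. Shifts close to 70 bp lie at the matching limit of 70 bp. The unadjusted count at +3 was 528, and the call count ran from 15 with a matching limit of 50 bp to 127 with the mean read position. Fits with 1 residual degree of freedom called 0 genes both in Ioc3-KO without WT1, WT2 or WT3 (496, 420 and 486 at unadjusted p under 0.05) and in WT1, WT2 and WT3 against the other 2 (215, 150 and 213), so the latter are no control for the count of 57.

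At the +1 nucleosome of Ioc3-KO, ALD5 alone was called (chromosome V, dyad 304008), a mitochondrial aldehyde dehydrogenase gene, with a shift of -67.3 bp (SE 1.03, adjusted p = 0.017). Its dyad lay at -89 bp from the start codon, against a wild-type mean of -21.7 ± 0.577 bp (SD, n = 3). PHO8, a phosphatase gene, lay at -36.0 bp in the knockout and -36.3 ± 5.51 bp (SD, n = 3) in wild type. At +2, 3 genes moved downstream: ISF1 by 69.0 bp (SE 1.87, adjusted p = 0.0221), YOR316C-A by 54.7 bp and the subtelomeric YHR214W by 52.3 bp. At +4, 49 genes were called, 38 downstream and 11 upstream. PRE1, a proteasome subunit gene, moved 64.0 bp (SE 1.74), TMA108 70.3 bp, IZH4 66.3 bp, FCY2, a purine-cytosine permease gene, 62.3 bp, ACF2 57.0 bp and AGA1, the a-agglutinin anchor subunit gene, 27.0 bp. PUN1, ROM1 and ERV2 had +4 shifts of -68.7, -38.0 and -36.7 bp. At +5, 30 genes were called, 22 downstream and 8 upstream, with NFT1 at 67.7 bp, MCH1 at 60.7 bp, ASH1, a repressor of mating-type switching, at -66.3 bp and SHC1 at -62.0 bp. The unadjusted counts were 172 at +1, 414 at +2, 437 at +4 and 348 at +5, and all 4 call counts were 0 without WT1, WT2 or WT3. Over other settings they ran from 0 to 2 at +1, 0 to 35 at +2, 18 to 157 at +4 and 0 to 115 at +5, with 0 at +2 without the fuzziest or least occupied quartile (410 and 420 unadjusted) and 0 at +5 with a matching limit of 50 bp (347 unadjusted).

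Genic nucleosomes were broader in Ioc3-KO. The median difference in the standard deviation of read positions, called fuzziness here, was 0.552 bp at -1, 0.540 bp at +1, 1.15 bp at +2, 1.61 bp at +3, 2.10 bp at +4 and 2.12 bp at +5, against -0.442 to 0.352 bp in the wild-type pools (exact permutation test, 1 pool against 3, two-sided, p = 0.25 at +1 to +5). At +4, fuzziness changed at 113 genes, higher at 108 and lower at 5. SHC1 rose by 14.3 bp (SE 1.89, adjusted p = 0.000136) from a wild-type mean of 30.0 bp. PTR3, an amino acid sensor gene, rose by 12.4 bp, MBA1 by 12.3 bp, MGT1 by 11.4 bp, NIT2 by 10.5 bp and YPT53 by 10.4 bp. The lower genes were FRK1 at -11.4 bp (SE 2.12, adjusted p = 0.00388), AIM25 at -7.32 bp, RPL7B at -6.94 bp, YHR033W at -6.59 bp and PCS60 at -6.14 bp. Of the cytosolic ribosomal protein genes, 48 were tested at +4, 4 rose (RPL17A 8.30 bp, RPL5 8.15 bp, RPS3 7.93 bp and RPS0B 7.50 bp) and 1 fell (RPL7B). Of 14 ribosome biogenesis genes, DBP2 and NOP12 rose by 7.66 and 6.18 bp. HIR3, a histone chaperone gene, rose by 7.72 bp, MEC1, the checkpoint kinase gene, by 7.93 bp, PRM5, a pheromone-regulated gene, by 8.64 bp and ARG8, of arginine synthesis, by 8.15 bp. At +5, 90 genes were called, 88 of them higher, and at +3, 28. Without WT1, WT2 and WT3 the +4 count was 5, 122 and 108, and fits of the same 1 residual degree of freedom gave 0, 6 and 4 calls in WT1, WT2 and WT3 against the other 2 (limma, 67 at unadjusted p under 0.05 in WT1). The +3 count was 87, 53 and 57 and the +5 count 94, 88 and 37 without WT1, WT2 and WT3.

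**Figure D2:**
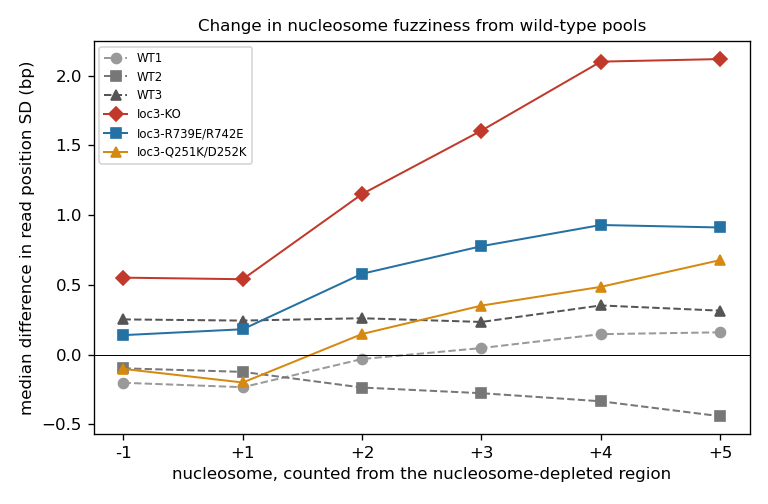
Median difference from wild type in the standard deviation of read positions, in bp (vertical axis), at the -1 to +5 nucleosomes (horizontal axis), wild-type pools dashed and each set against the other 2, Ioc3 pools solid. Ioc3-KO went from 0.540 bp at +1 to 2.12 bp at +5, and the wild-type pools lay between -0.442 and 0.352 bp.

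The comparison of Ioc3-R739E/R742E with wild type asked whether changing these residues of Ioc3 shifts nucleosomes. Its genic nucleosomes lay downstream by medians of 1.0 bp at +1, 1.67 bp at +2, 1.33 bp at +3, 0.667 bp at +4 and 0 bp at +5, with -1.0 bp at -1. The +1, +2 and +3 medians lay outside the wild-type pools, as did the upstream median at -1 (exact permutation test, 1 pool against 3, two-sided, p = 0.25). LEU9, of leucine synthesis, moved 42.7 bp downstream at +1 (chromosome XV, dyad 522942; SE 1.03, adjusted p = 0.033), and the subtelomeric YIL177C, a multicopy sequence, moved upstream with -56.0 bp (SE 1.29, adjusted p = 0.033). SPS1, a sporulation kinase gene, moved 49.0 bp at +2 (SE 0.938, adjusted p = 0.023) and NIT1 70.3 bp (SE 2.15, adjusted p = 0.0486). At +3, RPL36B moved 65.3 bp, YHR218W 41.3 bp, HIS5, of histidine synthesis, -58.7 bp (adjusted p = 0.0342), YET2 -69.0 bp and YHR214W -51.7 bp. The 4 genes called at +4 were overlapping Ty reading frames, YOR343W-A and YOR343W-B at 45.3 bp and YDR316W-A and YDR316W-B at -58.0 bp. The median fuzziness difference was 0.182 bp at +1 and 0.929 bp at +4. Fuzziness at +4 changed at 5 genes: FRK1 at -11.3 bp, ATG10, an autophagy gene, at 9.10 bp, HMLALPHA1 at 8.53 bp, and the Ty pair YGR161W-A and YGR161W-B at 17.9 bp. PHO8 had a +1 shift of 2.33 bp (SE 5.29, adjusted p = 0.913). Unadjusted counts were 168 at +1, 192 at +2, 233 at +3 and 176 at +4, and no gene was called at -1 or +5, with 147 and 137 genes at unadjusted p under 0.05. No position call remained without WT1, WT2 or WT3, and the fuzziness count at +4 was 3, 17 and 7 without them and 1 with robust eBayes. Over other settings the position counts ran from 0 to 4 at +1, 0 to 8 at +2, 0 to 14 at +3 and 0 to 9 at +4, with 8, 13 and 9 at +2, +3 and +4 with shifts centred per pool, where the +2 and +3 medians were 1.06 and 0.722 bp. Against WT1 as the only wild-type pool the +2 median was 1.0 bp.

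Ioc3-Q251K/D252K was compared with wild type for the same question at other residues. Its medians were 0.667 bp at +1, 1.33 bp at +2, 1.33 bp at +3, 1.0 bp at +4 and 0.333 bp at +5, with -0.333 bp at -1. The +1, +2 and +3 medians lay outside the wild-type pools (exact permutation test, 1 pool against 3, two-sided, p = 0.25), but after centring of each pool the +1, +2 and +3 medians were -0.111, 0.556 and 0.556 bp, with the +2 value above every wild-type pool (at most 0.333 bp) but smaller in size than the -0.667 bp of WT2. Against WT1 or WT3 as the only wild-type pool the +1 median was 0 bp. YLR225C moved upstream at +1 by -59.7 bp (SE 1.03, adjusted p = 0.0244), and the same nucleosome (chromosome XII, dyad 589127) is the -1 nucleosome of its divergent neighbour BUR2, a cyclin gene, called at 59.7 bp. The other -1 calls were DLD1, a lactate dehydrogenase gene, at 69.3 bp and RPL31B at -61.3 bp (SE 1.76, adjusted p = 0.0391 for both). PRE1 moved 69.0 bp at +4 (SE 1.74, adjusted p = 0.0172), and NFT1, the multicopy YLL067C and TPC1, a mitochondrial thiamine pyrophosphate carrier gene, moved 69.7, 41.0 and -62.0 bp at +5. The median fuzziness difference was -0.200 bp at +1 and 0.486 bp at +4, above every wild-type pool there (-0.335 to 0.352 bp), although the exact permutation test, 1 pool against 3 and two-sided, gave p = 0.5, since WT2 as the lone pool lay at -0.535 bp. The fuzziness of ZRT3, a vacuolar zinc transporter gene, rose by 10.6 bp at +4. PHO8 had a +1 shift of 5.33 bp (SE 5.29, adjusted p = 0.847). At +2 and +3 limma called 0 genes, with 207 and 238 at unadjusted p under 0.05, but 8 and 4 with shifts centred per pool or with robust eBayes, and 10 at +3 with the mean read position. All position calls of this pool were lost without WT1, WT2 or WT3 and with a matching limit of 50 bp, and the fuzziness count at +4 was 0, 5 and 3 without WT1, WT2 and WT3.

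Relative to each pool's median peak height, median peaks beside the depleted region were higher in all 3 Ioc3 pools than in any wild-type pool. The lead over WT1 was small in Ioc3-R739E/R742E, with median log2 peak heights at +1 of 0.556 and 0.542. On this scale, median deviations from the mean of all 6 pools were higher in every Ioc3 pool than in every wild-type pool at -1, +1, +2 and +3. Each had p = 0.1 (3 against 3, exact permutation test, two-sided, the smallest possible) and adjusted p = 0.154 over 20 measures. The median log2 difference in peak height at +1 was 0.25 in Ioc3-KO, 0.17 in Ioc3-Q251K/D252K and 0.11 in Ioc3-R739E/R742E, against 0.12, -0.07 and -0.03 in WT1, WT2 and WT3, each set against the other 2. At -1 it was 0.26, 0.20 and 0.12, against 0.12 in WT1, and at +4 and +5 all Ioc3 medians lay from -0.02 to 0.01. These values are relative to each pool's median peak height, which lay at log2 -0.12, -0.06 and -0.05 from wild type in Ioc3-KO, Ioc3-Q251K/D252K and Ioc3-R739E/R742E. As deposited, the +1 differences were 0.13, 0.11 and 0.06, against 0.09 in WT1. The value of Ioc3-R739E/R742E thus lay under that of WT1, which was set against the other 2 wild-type pools. The order of the pools as deposited was not examined at -1, +2 and +3. In Ioc3-KO, 5 genes rose at +1: DBP2, an RNA helicase gene (log2 1.69, SE 0.15, adjusted p = 0.0048), ZUO1, a ribosome-associated chaperone gene (1.33), YMR196W (1.16), GND2 (1.13) and the exosome gene RRP40. DBP2 and ZUO1 had very weak +1 peaks in wild type, at log2 -4.33 and -3.80 of the pool median. In Ioc3-Q251K/D252K, 17 genes were called, among them ARB1 (1.66), DBP2 (1.41), BUD21 (1.34), NOC4 (1.24), HST3 (1.24) and MPS3 (-1.06). HST3 and MPS3, the latter also called for fuzziness below, had very weak +1 peaks in wild type too. They lay at log2 -3.52 to -3.78 and -4.02 to -4.34 of the pool median. The silencing gene SIR4 (1.05), MRPL7 (1.12) and AMD2 (1.00) were called too, but 6 of the 17 lay in a segment of chromosome IV whose reads were higher throughout in this pool, by a median log2 of 0.92 at its 14 tested +1 nucleosomes against 0.17 elsewhere. Without that segment 3 genes were called in Ioc3-Q251K/D252K, and with occupancy not centred 2, and 1 in Ioc3-KO. At -1 limma called 0 genes in every genotype (405, 127 and 296 at unadjusted p under 0.05 in Ioc3-KO, Ioc3-R739E/R742E and Ioc3-Q251K/D252K). Calls were not confined to +1, since at +2 to +5 the counts were 2, 32, 7 and 0 in Ioc3-KO (228 unadjusted at +5) and 5, 24, 20 and 21 in Ioc3-Q251K/D252K. In Ioc3-R739E/R742E they were 0, 0, 2 and 0 (limma, 119, 103 and 81 at unadjusted p under 0.05 at +2, +3 and +5). Without the segment they were 2, 25, 6 and 0 in Ioc3-KO (226 unadjusted at +5) and 2, 7, 2 and 1 in Ioc3-Q251K/D252K. At +3 in Ioc3-KO 23 genes were higher and 9 lower, and without WT1, WT2 and WT3 the count was 5, 20 and 8. In Ioc3-R739E/R742E no gene was called at +1 (limma, 136 at unadjusted p under 0.05). The counts without WT1, WT2 and WT3 were 0, 68 and 61 for Ioc3-KO, 0, 16 and 15 for Ioc3-R739E/R742E and 0, 60 and 57 for Ioc3-Q251K/D252K, and fits of the same 1 residual degree of freedom gave 0, 16 and 14 calls in WT1, WT2 and WT3 against the other 2 (limma; without WT1 698, 264 and 475 at unadjusted p under 0.05, and 164 in WT1). edgeR on reads called 60 genes in Ioc3-KO, 107 in Ioc3-Q251K/D252K and 0 in Ioc3-R739E/R742E (122 at unadjusted p under 0.05). Fuzziness at +1 gave 0 calls in Ioc3-KO and Ioc3-R739E/R742E (limma, 121 and 114 at unadjusted p under 0.05) and 1 in Ioc3-Q251K/D252K, MPS3 at 17.96 bp, and without WT1 these counts were 13, 29 and 31. With the same 1 residual degree of freedom, WT1, WT2 and WT3 against the other 2 gave 32, 4 and 4.

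**Figure D3:**
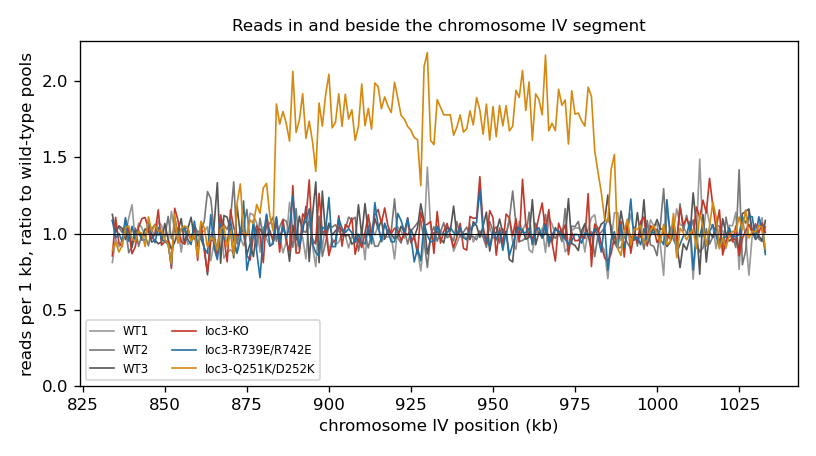
Reads per 1 kb as a ratio to the wild-type pools (vertical axis) along chromosome IV in kb (horizontal axis), 1 line per pool. In the segment from 884 to 983 kb the Ioc3-Q251K/D252K bins had a median of 1.78. Single bins of the other pools varied, up to 1.44 in WT1 at 930 kb, but their nucleosomes in the segment had median ratios from 0.976 to 1.02.

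Groups of genes were described by lists fixed beforehand and tested with camera. At +1 none of 23 lists passed in any genotype, with adjusted p from 0.315 to 0.926 in Ioc3-KO, from 0.624 to 0.985 in Ioc3-R739E/R742E and from 0.669 to 0.986 in Ioc3-Q251K/D252K. In Ioc3-KO, the 49 cytosolic ribosomal protein genes had a median +1 shift of 4.33 bp, against 1.0 bp in other genes. The 6 histone genes lay at -2.17 bp, 15 glycolysis and fermentation genes at -2.0 bp, 5 cyclin genes at -2.0 bp, 14 ribosome biogenesis genes at -0.833 bp and 20 amino acid synthesis genes at -0.667 bp. Adjusted over the list alone, 1 gene passed in each of the ribosomal protein, cyclin, subtelomeric and tandem promoter lists at +1. At +2 of Ioc3-KO the lists had adjusted p from 0.267 to 0.933, with ribosomal protein genes at 0.333 bp (53 genes), TCA and respiration genes at 4.33 bp (13) and mating genes at 4.33 bp (11, of which 5 passed adjusted over the list alone). At +3 of Ioc3-KO, 246 short genes lay at a median of 1.0 bp, against 3.0 bp in other genes (adjusted p = 0.0481; adjusted p = 0.825 with an estimated correlation), with 7 called downstream and 2 upstream, 7 and 3 adjusted over the list alone.

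The remaining lists at +3 of Ioc3-KO did not pass. Long genes lay at 4.0 bp (149 genes, 6 downstream and 1 upstream; 15 and 2 adjusted over the list alone), and ribosomal protein genes at 0.333 bp (52 genes, adjusted p = 0.078, 1 called each way; 3 each way adjusted over the list alone). Divergent promoters lay at 3.0 bp (799 genes, 25 downstream and 3 upstream) and tandem promoters at 2.67 bp (882 genes, 18 and 7), and 26 and 4, and 15 and 7, passed adjusted over the list alone. Subtelomeric genes lay at 2.33 bp (54 genes, 4 and 1; 8 and 1 adjusted over the list alone). Mating genes lay at 4.5 bp (10 genes, 4 adjusted over the list alone), amino acid genes at 5.0 bp (18), chaperone genes at 4.0 bp (5, with HSP104 called), cyclin genes at 3.5 bp (6) and galactose genes at 3.33 bp (10). Remodeler subunit genes lay at 2.83 bp (12, of which 2 passed adjusted over the list alone), tRNA-adjacent genes at 2.5 bp (48), stress genes at 2.33 bp (9), and glycolysis (11), phosphate (11) and TCA and respiration genes (13) at 2.0 bp. Sulfur genes lay at 1.33 bp (7), meiosis genes (17) and ribosome biogenesis genes (15) at 0.667 bp, general regulatory factor genes at -0.5 bp (6, with REB1 called) and mitochondrial ribosomal protein genes at -0.833 bp (16). In Ioc3-R739E/R742E no list passed at +2 or +3, with adjusted p from 0.133 and 0.105 upward. In Ioc3-Q251K/D252K, 328 short genes lay at 0.667 bp at +2, against 1.67 bp in other genes (adjusted p = 0.0499; adjusted p = 0.838 with an estimated correlation), and no list passed at +3. Histone genes, tested to +2, lay there at 3.67 bp in Ioc3-KO, 4.33 bp in Ioc3-R739E/R742E and -7.0 bp in Ioc3-Q251K/D252K (5 genes, none called).

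For fuzziness at +4, 1 list passed: 14 ribosome biogenesis genes in Ioc3-Q251K/D252K, with a median of 2.88 bp against 0.482 bp in other genes and 92.9% of members higher (adjusted p = 0.00713; adjusted p = 0.968 with an estimated correlation; 1 gene adjusted over the list alone). The same genes had 4.12 bp in Ioc3-KO (2 called, 4 adjusted over the list alone; list adjusted p = 0.182) and 1.68 bp in Ioc3-R739E/R742E (0 called). In Ioc3-KO, 10 phosphate genes had 4.49 bp (1 called, CTF19, and 6 adjusted over the list alone), 12 TCA and respiration genes 3.24 bp (ATP16 called, 4 adjusted over the list alone) and 10 mating genes 3.13 bp (PRM5 called). Of 148 long genes 16 rose, of 133 short genes 9, of 745 divergent promoter genes 52, with 2 lower, and of 815 tandem promoter genes 47, with 3 lower. In Ioc3-R739E/R742E the list p-values ranged from 0.781 to 0.979 after adjustment.

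Distances between neighbouring nucleosomes were compared in the same gene. In 1363 genes with +1 to +5 matched, the median +1 to +2 distance was 168 bp in each wild-type pool, 171 bp in Ioc3-KO, 169 bp in Ioc3-R739E/R742E and 170 bp in Ioc3-Q251K/D252K. The gene-wise median differences were 2.33, 0.667 and 1.0 bp. The -1 to +1 distance, across the depleted region (1311 genes), was longer by medians of 2.0, 2.67 and 1.33 bp. The +4 to +5 distance differed by -1.33, -1.0 and -0.667 bp, and the +2 to +3 distance by 0.333, -0.333 and 0 bp. Wild-type pools, each set against the other 2, differed by 0 bp for +1 to +2 and by -0.5 to 0.5 bp for -1 to +1. They differed by -0.5 to 0 bp for +4 to +5 and by -0.5 to 0.5 bp for +2 to +3, which covers all Ioc3 values there. The whole +1 to +5 length differed by -0.667, -1.33 and -0.333 bp, against -1.0 to 1.0 bp in the wild-type pools. No gene was called for either of the first 2 distances (limma; 215, 115 and 127 genes at unadjusted p under 0.05 for +1 to +2, and 183, 162 and 143 across the depleted region). In all adjacent listed dyads 120 to 220 bp apart, without genes, the median differed by -0.333 bp in each genotype, as it was 165 bp in WT1 and 164 bp in all other pools. The mean of these distances was 164.3, 164.3 and 164.2 bp in Ioc3-KO, Ioc3-R739E/R742E and Ioc3-Q251K/D252K, under each wild-type pool (164.4 to 164.7 bp; 3 against 3, exact permutation test, two-sided, p = 0.1, the smallest possible).

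All 3 Ioc3 pools were set against all 3 wild-type pools to ask what the genotypes shared. Over genes, the Ioc3 pools lay downstream by medians of 0.833 bp at +1, 1.92 bp at +2, 1.83 bp at +3 and 1.28 bp at +4, above every wild-type pool (3 against 3, exact permutation test, two-sided, p = 0.1 each, the smallest possible, adjusted p = 0.154 over 20 measures). Median fuzziness was higher by 0.949, 1.14 and 1.26 bp at +3, +4 and +5 (3 against 3, exact permutation test, two-sided, p = 0.1, adjusted p = 0.154). At +2, 5 genes moved downstream: OYE3 by 65.0 bp (SE 3.89, adjusted p = 0.00311), ASH1 by 58.7 bp (SE 3.13, adjusted p = 0.00246), the subtelomeric multicopy YJL225C by 38.0 bp, DAK1, a dihydroxyacetone kinase gene, by 30.7 bp (SE 1.51) and MST1, a mitochondrial threonyl-tRNA synthetase gene, by 9.67 bp (SE 1.04, adjusted p = 0.0473). YHR218W moved 47.0 bp at +3, and limma called 0 genes at +1 (234 at unadjusted p under 0.05), 4 without WT1 and 3 without Ioc3-Q251K/D252K. With each of the 6 pools left out in turn, the +2 count stayed at 3 to 5 (3 without WT3), and the +3 count was 0 without WT2 (222 unadjusted), 2 without WT3 or Ioc3-KO, 3 without WT1 or Ioc3-R739E/R742E and 6 without Ioc3-Q251K/D252K. Fuzziness at +4 rose at PTR3 (8.35 bp), ZRT3 (7.71 bp), PRM5 (6.94 bp), BMT5 (6.65 bp), ARB1 (6.65 bp) and USO1 (6.12 bp) and fell at FRK1 (-9.85 bp, SE 1.68, adjusted p = 0.0127), and at +3 it rose at YLR415C (adjusted p = 0.0293). At +1, +2 and +5 limma called 0 genes for fuzziness (147, 217 and 240 at unadjusted p under 0.05), and at +2, 3 without WT1 and 1 without WT3 or Ioc3-KO. The +4 fuzziness count was 0 without WT2 or WT3 (165 and 210 unadjusted), 1 without WT1, 3 without Ioc3-Q251K/D252K, 4 without Ioc3-KO and 11 without Ioc3-R739E/R742E. The +3 fuzziness count was 0 without WT2, WT3, Ioc3-KO or Ioc3-R739E/R742E (165, 215, 185 and 228 unadjusted), 2 without WT1 and 6 without Ioc3-Q251K/D252K. Peak height at +1 rose at MTC7 (log2 0.92, SE 0.11, adjusted p = 0.0196) and ROM1 (0.75, SE 0.10), with 0 genes called without WT2, Ioc3-KO or Ioc3-Q251K/D252K (347, 334 and 400 unadjusted), 1 without WT3, 49 without WT1 and 40 without Ioc3-R739E/R742E. The pools of both groups did not overlap at 445 genes at +2 (23.5%; 385 downstream), 428 at +3 (23.1%; 369 downstream), 278 at +1 (13.9%) and, for fuzziness at +4, 331 (19.2%; 290 higher), where chance gives 10%.

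Differences between the genotypes were tested directly, with 1 pool in each arm and the error taken from the wild-type pools. At +1, ALD5, YIL177C and LEU9 differed between Ioc3-R739E/R742E and Ioc3-KO (62.0, -58.0 and 43.0 bp; SE 1.26 for ALD5), and ALD5 and YLR225C between Ioc3-Q251K/D252K and Ioc3-KO (72.0 and -57.0 bp). At +3, NIT2, SKM1, PTH4, SNX3, RQT4 and ATP16 lay less far downstream in both point mutants than in the knockout, with differences for NIT2 of -61.0 and -62.0 bp (SE 1.09). DLD3 and APQ12 lay less far upstream in both (66.0 and 67.0 bp for DLD3, 39 and 40 bp for APQ12). SPR6 had lower fuzziness at +4 than in the knockout in both, by -18.2 bp (SE 2.48) and -15.8 bp (SE 2.48), and SHC1 in Ioc3-R739E/R742E (-13.3 bp). The point mutants differed from each other at 0 genes at +1 and +3 (limma, 99 and 132 at unadjusted p under 0.05) and at 1 gene at +2, SPS1 (-57.0 bp). All of these position counts were 0 without WT1, WT2 or WT3 (limma; 272 to 292 at unadjusted p under 0.05 at +3 for Ioc3-R739E/R742E against Ioc3-KO), so single genes are not established as differing. The +4 fuzziness counts, 3 and 2, were 1 and 1 without WT1, 11 and 20 without WT2 and 8 and 13 without WT3.

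Shifts were correlated across genes between genotypes, where genes are not independent replicates and the shared wild-type mean alone gives a positive value. At +2 Pearson's r was 0.374 for Ioc3-KO with Ioc3-R739E/R742E, 0.325 for Ioc3-KO with Ioc3-Q251K/D252K and 0.435 between the point mutants (Spearman's rho 0.454, 0.449 and 0.456). Simulation from the shared mean gave r = 0.243 with an upper limit of 0.413 and rho = 0.219 with an upper limit of 0.268. The covariances at +2 were 26.9, 24.6 and 25.6, against 12.2 simulated. At +3 r was 0.390, 0.421 and 0.315, against a simulated r of 0.252, and rho was 0.477, 0.492 and 0.462, against a simulated rho of 0.218. There the covariances were 29.3, 30.4 and 16.5, against 8.89. All r at +1 and +3 lay under the upper simulated limits of 0.385 and 0.443, and at +2 only the r between the point mutants lay above its limit, while all rho lay above the upper simulated limits of 0.269, 0.268 and 0.258 at +1, +2 and +3. At +1 r was 0.272, 0.332 and 0.302, against a simulated r of 0.247, and rho was 0.371, 0.408 and 0.376, against a simulated rho of 0.214, with covariances of 21.1, 26.8 and 23.8 against 17.2. A different wild-type pool was then used for each genotype, a single pool in place of the mean of 3. With these references r fell to means of 0.151, 0.123 and 0.160 at +2, 0.220, 0.238 and 0.110 at +3 and 0.0333, 0.0810 and 0.0561 at +1, and rho to means from 0.121 at +1 to 0.306 at +3.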

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

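The tests of genotype differences at +2 and +3, the marker gene reads and mitochondrial reads, the search for the segment, and the tests below of uniform broadening, of the Ioc3 genotype, of mapping and of 1 extra copy were chosen only after the result was seen. In contrasts of 1 pool with 1 pool, with the error taken from the wild-type pools, the point mutants differed from the knockout at +1 at 3 genes for Ioc3-R739E/R742E (ALD5, YIL177C and LEU9) and 2 for Ioc3-Q251K/D252K (ALD5 and YLR225C). At +2 they differed at 6 genes (ISF1, SPS1, NIT1, HIM1, YHR214W and YOR316C-A) and at 2 genes (YHR214W and YOR316C-A), and the point mutants differed from each other at 1 gene (SPS1). At +3 they differed at 15 and 14 genes, among them NIT2, SKM1, PTH4, SNX3, RQT4, ATP16, DLD3 and APQ12 in both. All of these counts were 0 without WT1, WT2 or WT3 (limma, 136 to 292 at unadjusted p under 0.05), so the difference at single genes is not established.

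In Ioc3-KO, genic nucleosomes lay downstream and were broader. The argument against a broadening by digestion or depth that is equal at every nucleosome is that the rise in fuzziness at +4 exceeded that at +1 by 1.56 bp. It was at most 0.381 bp in a wild-type pool. A digestion effect that differs along the gene was not tested and stays open. Extra closely spaced calls, which made up 18.3% of gaps in Ioc3-KO against 14.0% to 15.2% in wild type, are argued against by the 1492 genes without a second call within 120 bp, where the +3 shift was 3.33 bp, against at most 0.5 bp in a wild-type pool. A change of the Ioc3 genotype may account for the shift, since the smallest +2 or +3 median of the point-mutant pools was 1.33 bp, beyond the 0.5 bp of the wild-type pools, although after centring of each pool the +2 median of Ioc3-Q251K/D252K (0.556 bp) was smaller in size than the -0.667 bp of WT2. Fuzziness at +4 in Ioc3-R739E/R742E and Ioc3-Q251K/D252K (0.929 and 0.486 bp) also lay above every wild-type pool (at most 0.352 bp), with p = 0.25 and 0.5 in exact two-sided permutation tests of 1 pool against 3, and open remain the culture and preparation of each single Ioc3 pool, which could not be separated from its genotype.

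Reads of Ioc3-Q251K/D252K stepped up over chromosome IV from 884001 to 983000, 99 kb with 49 whole genes from GCD6 to YDR261W-A, among them the histone genes HTA1 and HTB1, SIR4, ADR1 and RAD9. The edges are those of the run rule, and some bins outside them were raised too, at 1.30 and 1.33 at 880 and 881 kb and 1.42 and 1.52 at 986 and 987 kb. The 566 nucleosomes of the segment had a median of 1.76 times wild type (SE 0.0129), a signal in reads that the position tests do not use. Mapping or annotation is argued against by the other pools, at most 1.02 in the segment, and higher occupancy of well positioned nucleosomes by the weakest quartile, which stood at 1.82 (SE 0.0565). Inside over outside the segment the ratio was 1.79, and 1.85 in the weakest quartile, so 1 extra copy in all cells of both replicates and an extra copy in a part of them cannot be told apart, because duplicate removal, which lowers ratios, is not stated. A higher copy number of the segment remains a hypothesis, and no link to the Ioc3 genotype was tested.

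Mitochondrial reads, outside all fits, made up 278 ppm of assigned reads in Ioc3-KO, 208 in Ioc3-R739E/R742E and 295 in Ioc3-Q251K/D252K, against 140 ± 23.6 (SD, n = 3 pools) in wild type. The URA3 coding region (chromosome V, 116167 to 116970) had 698 reads in Ioc3-KO and no listed nucleosome in the other pools.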

How the results depend on the processing

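Chosen only after the data were seen were the mean read position, the removal of weak calls, edgeR on reads, the genes outside the chromosome IV segment, each wild-type pool as the only reference, the mean of all adjacent dyads, the genotype differences without a pool, and all tests of position and occupancy calls at -1 and +2 to +5, of fuzziness at +3 to +5 and, for 3 against 3 pools, of occupancy at +1 and of fuzziness at +1 to +5. Over 1005 values under alternatives, 579 stayed as reported, 108 moved, 138 counts became larger, 172 smaller and 8 values reversed. Of the reversed values, 2 in each genotype set all adjacent dyads against the +1 to +2 distance, which is another quantity. Median shifts at +2 and +3 kept their downstream direction in 96 of 96 alternatives, of which 24 moved: Ioc3-KO had 1.39 to 3.23 bp at +2 and 1.39 to 3.37 bp at +3, Ioc3-R739E/R742E 1.0 to 2.0 and 0.722 to 1.5 bp, and Ioc3-Q251K/D252K 0.556 to 2.0 and 0.556 to 2.0 bp. Counts of called genes in single genotypes rest on the spread of 3 wild-type pools, so they depend on each of them. No paired analysis was possible because both replicates of a group were joined in 1 list, and because the labels do not say which wild-type pool was handled beside which genotype, so a replicate block was not run. The planned dyad at the middle of the listed start and end was void, since these are always 1 bp apart. With a median of 133 to 139 reads per nucleosome, the mean read position had a median standard error of 2.77 bp. This error belongs to 1 nucleosome in 1 pool and does not apply to summits. It is also no measure of the error of a median over genes. It thus cannot judge the Ioc3-KO medians of 3.23 and 3.37 bp at +2 and +3 with the mean read position. Median shifts are values over many genes and are not established for single genes. Unless the construction of a setting is named below, the cause of a change was not tested.

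With shifts centred per pool, which by construction removes any shift common to a pool's nucleosomes, the -1 to +5 medians were -1.94, -0.278, 1.39, 1.39, 0.722 and -0.611 bp in Ioc3-KO, -1.61, 0.389, 1.06, 0.722, 0.0556 and -0.611 bp in Ioc3-R739E/R742E and -1.11, -0.111, 0.556, 0.556, 0.222 and -0.444 bp in Ioc3-Q251K/D252K. The +1 medians of Ioc3-KO and Ioc3-Q251K/D252K reversed. In all adjacent dyads 120 to 220 bp apart, without genes, the difference from wild type was -0.333 bp in each genotype, with a sign opposite to the +1 to +2 distance. The medians were 165 bp in WT1 and 164 bp in all other pools. The mean of all adjacent dyads gave -0.246, -0.273 and -0.357 bp in Ioc3-KO, Ioc3-R739E/R742E and Ioc3-Q251K/D252K, with every Ioc3 pool under every wild-type pool. All adjacent dyads are another quantity than the +1 to +2 distance, so the opposite sign does not contradict it. Within genes, in the same order, the +3 to +4 distance differed by -1.0, -0.667 and -0.667 bp. The +4 to +5 distance differed by -1.33, -1.0 and -0.667 bp. The cause of the opposite signs was not tested.

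Counts of +1 position calls in the order Ioc3-KO, Ioc3-R739E/R742E and Ioc3-Q251K/D252K were 0, 0 and 0 with a matching limit of 50 bp, with the mean read position and with a trend on mean fuzziness, and 0, 1 and 0 without the fuzziest quartile and without the lowest quartile of occupancy, where fewer genes were tested. The untested rule of 20 bp outside the wild-type range gave 36, 33 and 35, against 39, 39 and 53 in the wild-type pools. Each wild-type pool was set against the range of the other 2, and each Ioc3 pool against that of all 3. A range of fewer pools is narrower and gives more such genes, so these counts are not like for like. The consensus from wild-type pools gave 0 in Ioc3-KO and 4 in Ioc3-R739E/R742E, and the limit of 90 bp 2 in Ioc3-KO. A minimum width of 250 bp, no minimum width and weak calls removed gave 0 in both point mutants. With weak calls removed, all 3 Ioc3 pools against wild type gave 1. The distance calls were 1 in Ioc3-KO (-1 to +1, minimum width 250 bp) and 3 in Ioc3-Q251K/D252K (+1 to +2, matching limit 90 bp). Of the gene lists, 1 passed at the +2 nucleosome in Ioc3-Q251K/D252K.

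Counts of position calls at -1, +2, +3, +4 and +5 (limma), in this order, were as reported 0, 3, 57, 49 and 30 in Ioc3-KO, 0, 2, 5, 4 and 0 in Ioc3-R739E/R742E and 3, 0, 0, 1 and 3 in Ioc3-Q251K/D252K. With the consensus from wild-type pools they were 2, 6, 86, 73 and 33 in Ioc3-KO, 0, 1, 8, 4 and 0 in Ioc3-R739E/R742E and 3, 0, 3, 6 and 0 in Ioc3-Q251K/D252K. With a matching limit of 50 bp they were 0, 1, 15, 18 and 0 in Ioc3-KO, 0, 1, 0, 0 and 0 in Ioc3-R739E/R742E and 0, 0, 0, 0 and 0 in Ioc3-Q251K/D252K. At 90 bp they were 0, 13, 48, 52 and 32 in Ioc3-KO, 1, 1, 5, 5 and 0 in Ioc3-R739E/R742E and 5, 0, 0, 2 and 3 in Ioc3-Q251K/D252K. The mean read position gave 0, 32, 127, 157 and 115 in Ioc3-KO, 0, 0, 11, 3 and 0 in Ioc3-R739E/R742E and 2, 0, 10, 8 and 1 in Ioc3-Q251K/D252K. A minimum width of 250 bp gave 1, 5, 33, 26 and 8 in Ioc3-KO, 0, 1, 3, 3 and 1 in Ioc3-R739E/R742E and 0, 0, 1, 1 and 1 in Ioc3-Q251K/D252K. No minimum width gave 0, 35, 51, 97 and 93 in Ioc3-KO, 0, 0, 3, 3 and 0 in Ioc3-R739E/R742E and 0, 0, 0, 2 and 0 in Ioc3-Q251K/D252K. Robust eBayes gave 0, 27, 118, 81 and 35 in Ioc3-KO, 4, 8, 14, 9 and 2 in Ioc3-R739E/R742E and 3, 8, 4, 5 and 4 in Ioc3-Q251K/D252K. Centring per pool gave 3, 22, 74, 66 and 34 in Ioc3-KO, 4, 8, 13, 9 and 2 in Ioc3-R739E/R742E and 3, 8, 4, 5 and 4 in Ioc3-Q251K/D252K. Removal of weak calls gave 1, 7, 124, 135 and 66 in Ioc3-KO, 0, 1, 0, 7 and 0 in Ioc3-R739E/R742E and 1, 0, 0, 1 and 4 in Ioc3-Q251K/D252K. Without the fuzziest quartile, where fewer genes were tested, they were 0, 0, 46, 19 and 11 in Ioc3-KO, 1, 0, 0, 0 and 0 in Ioc3-R739E/R742E and 0, 0, 0, 0 and 1 in Ioc3-Q251K/D252K. Without the lowest quartile of occupancy, likewise with fewer genes, they were 0, 0, 54, 49 and 22 in Ioc3-KO, 0, 0, 0, 6 and 0 in Ioc3-R739E/R742E and 0, 0, 0, 2 and 1 in Ioc3-Q251K/D252K. Without the chromosome IV segment they stayed as reported, except for 51 at +4 in Ioc3-KO. Where a count was 0 at -1 and +2 to +5, the genes at unadjusted p under 0.05 were 122 to 688 at -1, 410 to 420 at +2 and 347 at +5 in Ioc3-KO. In Ioc3-R739E/R742E they were 73 to 470 at -1, 172 to 478, 192 to 529, 164 to 170 and 101 to 410 at +2 to +5, and in Ioc3-Q251K/D252K 74 to 448 at -1, 66 to 554, 205 to 663, 158 to 160 and 132 to 401.

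Occupancy calls at +1 in Ioc3-KO and Ioc3-Q251K/D252K were 23 and 27 at 50 bp, 17 and 31 with robust eBayes, 60 and 107 with edgeR on reads, and 1 and 2 with occupancy not centred, and without the chromosome IV segment 3 were called in Ioc3-Q251K/D252K. At +2 to +5 the counts without that segment were 2, 25, 6 and 0 in Ioc3-KO (limma, 226 at unadjusted p under 0.05 at +5) and 2, 7, 2 and 1 in Ioc3-Q251K/D252K. Fuzziness calls at +1 were 2 in each point mutant with robust eBayes and 1 in Ioc3-R739E/R742E at 50 bp. At +4 robust eBayes gave 1 in Ioc3-R739E/R742E.

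Median shifts moved as follows. Against WT1 as the only wild-type pool, with positions in whole bp, Ioc3-KO had 0.0 bp at -1 and 2.0 bp at +2 and +3, Ioc3-R739E/R742E 1.0 bp at +2, and Ioc3-Q251K/D252K 0.0 bp at -1 and +1 and 1.0 bp at +2. Against WT2 alone, Ioc3-KO had 3.0 bp at +2 and 0.0 bp at +5, Ioc3-R739E/R742E 2.0 bp at +2 and -1.0 bp at +5, and Ioc3-Q251K/D252K -1.0, 1.0 and 2.0 bp at -1, +1 and +2. Against WT3 alone, Ioc3-KO had 3.0 bp at +2, Ioc3-R739E/R742E 2.0 bp at +2, and Ioc3-Q251K/D252K 0.0 bp at -1 and +1, 2.0 bp at +2 and +3 and 1.0 bp at +5. The other medians against a single pool, 33 of 54, stayed within the wild-type spread of those reported. With the consensus from wild-type pools, +1 was 0.667 bp in Ioc3-KO and 0.333 bp in Ioc3-Q251K/D252K. With the mean read position, Ioc3-KO had 0.988 bp at +1, 3.23 bp at +2 and 3.37 bp at +3, Ioc3-R739E/R742E -1.42 bp at -1 and 1.42 bp at +1, and Ioc3-Q251K/D252K 0.613 bp at +1. With a minimum width of 250 bp, Ioc3-KO had -0.333 bp at -1, 0.667 bp at +1 and 1.33 bp at +4, Ioc3-R739E/R742E 0.667 bp at +1, and Ioc3-Q251K/D252K 0.333 bp at +1 and 1.0 bp at +2. With no minimum width, Ioc3-KO had 0.667, 2.0 and 1.67 bp at +1 to +3, Ioc3-R739E/R742E 0.667 bp at +1, and Ioc3-Q251K/D252K 0.333, 1.0 and 0.667 bp at +1 to +3. With weak calls removed, Ioc3-KO had 0.667 bp at +1 and 0.0 bp at +5, Ioc3-R739E/R742E 0.667 bp at +1, and Ioc3-Q251K/D252K 0.333 bp at +1 and -0.333 bp at +5.

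Distances moved with weak calls removed to 1.33 bp (-1 to +1), 0.0 bp (+2 to +3), -1.33 bp (+3 to +4) and -1.67 bp (+4 to +5) in Ioc3-KO, to 2.0 bp (-1 to +1) in Ioc3-R739E/R742E, and to 0.667 bp (-1 to +1), -1.0 bp (+3 to +4) and -1.0 bp (+4 to +5) in Ioc3-Q251K/D252K. As means over genes, Ioc3-KO had 2.24 bp (+1 to +2) and -1.67 bp (+4 to +5), Ioc3-R739E/R742E 0.366 bp (+1 to +2), and Ioc3-Q251K/D252K 0.670 bp (-1 to +1), 1.28 bp (+1 to +2) and -0.938 bp (+4 to +5). In genes with the 2 nucleosomes matched, Ioc3-KO had 2.0 bp (+1 to +2) and -0.667 bp (+3 to +4). With separate wild-type pools, the correlations of Ioc3-KO with Ioc3-R739E/R742E, of Ioc3-KO with Ioc3-Q251K/D252K and between the point mutants were 0.0333, 0.0810 and 0.0561 at +1, 0.151, 0.123 and 0.160 at +2 and 0.220, 0.238 and 0.110 at +3. By construction no wild-type noise is then shared, and each reference is 1 pool instead of the mean of 3. These 2 parts of the fall were not separated.

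Leaving out 1 wild-type pool at a time gave 0 to 0 position calls at +1 in each genotype and 0 to 0 at -1 and at +2 to +5 (limma; 420 to 496 at unadjusted p under 0.05 at +3 in Ioc3-KO), where only 1 residual degree of freedom was left. Occupancy calls at +1 went from 0 without WT1 to 68 without WT2 in Ioc3-KO, 0 to 16 in Ioc3-R739E/R742E and 0 to 60 in Ioc3-Q251K/D252K. At +2 to +5 they went from 0 to 28, 5 to 20, 3 to 23 and 3 to 80 in Ioc3-KO, 0 to 6, 0 to 1, 2 to 4 and 1 to 16 in Ioc3-R739E/R742E, and 0 to 27, 19 to 22, 14 to 34 and 21 to 72 in Ioc3-Q251K/D252K (limma, at least 63 at unadjusted p under 0.05), and at -1 from 0 to 0 in each (limma, 85 to 574 at unadjusted p under 0.05). Genotype differences in position at +1 to +3 went from 0 to 0 (limma, 136 to 292 at unadjusted p under 0.05). In fuzziness at +4 they went from 1 to 11 for Ioc3-R739E/R742E and 1 to 20 for Ioc3-Q251K/D252K against Ioc3-KO and 0 to 4 between the point mutants. Fuzziness calls at +1 went from 0 to 13, 0 to 29 and 0 to 31, highest without WT1, and at +4 in Ioc3-KO from 5 without WT1 to 122 without WT2. Fuzziness calls at +3, +4 and +5 went from 53 to 87, 5 to 122 and 37 to 94 in Ioc3-KO, 2 to 4, 3 to 17 and 1 to 5 in Ioc3-R739E/R742E, and 0 to 4, 0 to 5 and 0 to 6 in Ioc3-Q251K/D252K (limma, at least 98 at unadjusted p under 0.05). The 3 against 3 count at +1 went from 0 to 4, with 4 without WT1 and 3 without Ioc3-Q251K/D252K. The other 3 against 3 counts went from 1 to 5 at -1, 3 to 5 at +2, 0 to 6 at +3, 0 to 4 at +4, 2 to 5 at +5, 0 to 0, 0 to 3, 0 to 6, 0 to 11 and 0 to 0 for fuzziness at +1 to +5 (limma; at least 114 and 159 at unadjusted p under 0.05 at +1 and +5), and 0 without WT2 to 49 without WT1 for occupancy at +1. Distances in Ioc3-KO went from 1.5 to 2.5 bp (-1 to +1), 2.0 to 2.0 bp (+1 to +2), 0.0 to 0.5 bp (+2 to +3) and -1.5 to -1.0 bp (+4 to +5). In Ioc3-R739E/R742E they went from 2.0 to 3.0 bp (-1 to +1), 0.5 to 0.5 bp (+1 to +2), -0.5 to 0.0 bp (+2 to +3) and -1.0 to -0.5 bp (+3 to +4). In Ioc3-Q251K/D252K the +1 shift was 0.5 bp and the +3 to +4 distance went from -1.0 to -0.5 bp.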

Other observations

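The linker test and the array test below were planned before their results were seen, except that the linker test's verdict by sign was set afterwards, and the digestion tests, the splits and the calls at -1, +4 and +5 were chosen only after the result was seen. Upstream and far downstream nucleosomes also held genes shared by the Ioc3 genotypes, in the comparison of 3 with 3 pools by limma. At -1, YOR1, a multidrug transporter gene, moved by -53.3 bp (SE 1.73, adjusted p = 0.000682), ASH1 by -48.7 bp (SE 2.42, adjusted p = 0.00319) and HNT3 by -10.7 bp (adjusted p = 0.0358), with 203 genes at unadjusted p under 0.05. At ASH1 the -1 nucleosome thus lay upstream and the +2 nucleosome 58.7 bp downstream, while its +1 shifts of 21, 20 and 3 bp in Ioc3-KO, Ioc3-R739E/R742E and Ioc3-Q251K/D252K were not called. At +5, TPC1 moved by -62.3 bp (SE 1.57, adjusted p = 4.31e-05) and ILS1, an isoleucyl-tRNA synthetase gene, by -20 bp. GND1, of the pentose phosphate pathway, moved by 56.3 bp, MPC54, a meiotic spindle pole gene, by 46.0 bp (adjusted p = 0.00198), RMA1 by 31.3 bp and ATH1, the acid trehalase gene, by 19.7 bp. The 2 genes called at +4, YDR210W-A and YDR210W-B, are overlapping Ty reading frames and shared 1 nucleosome at -43.3 bp. With each of the 6 pools left out in turn, the count at -1 was 1 without WT3, 5 without Ioc3-Q251K/D252K and 2 without Ioc3-R739E/R742E, and the count at +5 was 2 without WT3 or Ioc3-Q251K/D252K, 3 without Ioc3-R739E/R742E and 4 or 5 without the others. The +4 count was 0 without WT2 or Ioc3-KO (limma, 179 and 216 at unadjusted p under 0.05), 1 without WT1, WT3 or Ioc3-Q251K/D252K and 4 without Ioc3-R739E/R742E.

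Relative to each pool's median peak height, median peaks beside the depleted region were higher in the Ioc3 pools than in WT1, WT2 and WT3. The rises of WT1 (log2 0.116 at +1) and Ioc3-R739E/R742E (0.115) have different references, since the wild-type mean for the latter includes WT1. With WT1 as the lone pool against WT2, WT3 and Ioc3-R739E/R742E, its difference was 0.065. The median peak at +1 was also higher in Ioc3-R739E/R742E, at log2 0.556 against 0.542 in WT1. A digestion level differing between pools stays open for Ioc3-R739E/R742E, because its lead over WT1 was small and this genotype has 1 pool. For Ioc3-KO and Ioc3-Q251K/D252K, whose smaller rise was 0.170, digestion and genotype cannot be told apart, because each genotype has 1 pool and the rise faded towards +5 as it did in WT1.

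One hypothesis was that closely spaced +1 and +2 nucleosomes move apart more without Ioc3. The test used the +2 shift alone, without the shift of +1, so the change in their distance was not measured. Over 1828 genes the knockout +2 shift was 2.0 bp in the quartile with the shortest wild-type distance (155 bp) and 3.0 bp in the longest (182 bp). The difference was -1.0 bp (bootstrap over genes, SE 0.458, 1000 draws). The bound written beforehand, a difference no larger in size than for WT2 minus WT3 (0 bp), was not met. The sign is opposite to the hypothesis for the +2 shift. The SE covers genes of 1 knockout pool and no spread between pools, so the hypothesis is not decided. Another hypothesis was that arrays move as a unit. Across 1760 genes the +2 and +3 shifts of Ioc3-KO had Pearson's r = 0.192 at the lowest when 1 wild-type pool was left out, and 0.228 with all 3, against -0.0664 to -0.0632 in the wild-type pools and 0.127 and 0.132 in Ioc3-R739E/R742E and Ioc3-Q251K/D252K. Genes are not independent, and a joint move of neighbouring nucleosomes may be part of the knockout pattern.

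The 6 pools can be split 3 against 3 in 10 ways, too few for a share under 0.05. For shifts at +1 and fuzziness at +1, +2 and +5 the real split gave 0 calls and the highest other 1, 1, 0 and 0. A count of 0 is met by all 10 splits whatever the data, so it decides nothing, and the genes at unadjusted p under 0.05 were 234, 147, 217 and 240 in the real split, against at most 96, 104, 104 and 103 in the others. For shifts at +3 the real split gave 1 and the highest other 1, so 3 gave as many. In each of the other 7 measures 1 split gave as many, the real one. Its counts were 3 at -1, 5 at +2, 2 at +4 and 6 at +5, with the highest other at 1, 0, 1 and 1, and 1 for fuzziness at +3, 7 for fuzziness at +4 and 2 for occupancy at +1, with the highest other at 0 in all 3.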
